A study of Mus musculus with 8 samples.

How the data were processed

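RNA was measured on 8 Agilent one-colour mouse expression arrays, 1 array for each of 8 groups. The cells were LSK cells, the lineage-negative, c-Kit-positive, Sca-1-positive marrow fraction that holds stem cells and early progenitors. Per the labels, donor CD45.2 stem cells with wild-type or floxed Ezh2 and an inducible Cre were given RUNX1S291fs or an empty retrovirus and grafted into irradiated C57BL/6 recipients beside wild-type CD45.1 marrow. Ezh2 was then deleted. The groups are named here WT, Ezh2_deleted, RUNX1_mutant and Double_mutant for month 4 CD45.2 cells. Double_MDS and Double_MDS_ML are CD45.2 cells of single double-mutant mice with myelodysplastic syndrome (MDS), the second with MDS and myeloid leukemia. CD45.1_in_RUNX1_mutant and CD45.1_in_double_mutant are wild-type competitor cells from the marrow of RUNX1_mutant and Double_mutant recipients. Per the labels, month 4 arrays held pooled cells of 2 to 4 mice. The age of the moribund mice is not given in the sources used here.

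Per the labels' protocols, cells were sorted on a FACSAriaII, RNA was extracted with RNeasy Plus Mini kits, and 20 ng of total RNA with a one-colour spike mix was amplified and labelled with Cy3 by the Low Input Quick Amp kit. Per the file headers, the arrays (design 028005) were read with Agilent Feature Extraction 10.7.1.1. Hybridisation settings are not given in the sources used here. Per the file headers, the processed signal is a fluorescence intensity with background and spatial trend removed within each array, and no scaling between arrays. Per the file headers, the median spot and local background columns are raw pixel intensity. The series table as deposited by the authors holds linear signal. Set against the scanner values, each of its 8 columns was the processed signal divided by 1 factor per array (99.7% to 99.8% of probes lay within 0.01 log2 of that ratio), with a 75th percentile of 1.00 to 1.01 and no centring on genes. All 8 columns were used and 0 were left out.

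Each array held 62976 spots, of which 59305 were not controls and gave 55681 probes. Spots of a probe printed more than once were averaged. The values used throughout are log2 processed signal minus the 75th percentile of the array, so a probe at that percentile has the value 0. A probe was called well above background where the scanner software marked it so. Gene names came from the RefSeq gene table of assembly GRCm38.p6, used for names only, matched through transcript accessions. In all, 27235 of 55681 probes received a name, covering 20660 genes, and 28446 received none. For a gene with more than 1 probe (5476 genes) the probe with the highest mean was kept. As single arrays carry no count depth, their number limits the precision. Between 43.9% (CD45.1_in_RUNX1_mutant) and 55.3% (WT) of probes were well above background, and 0 probes were saturated. The median log2 SD between repeat spots of a probe was 0.0529 to 0.0676, which covers spotting only.

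Since no group has a second array, differences between single groups have no test. An additive model over the 8 arrays did give tests: terms for Ezh2 deletion (4 of 8 arrays), RUNX1S291fs (4 of 8) and moribund stage (2 of 8), fitted with limma 3.58.1 in R 4.3.3 to the 13545 genes well above background on at least 3 arrays. Its spread comes from the 3 wild-type arrays, the 2 moribund arrays and departures from additivity (4 residual degrees of freedom, 3.12 prior). The stage term takes up the mean of both moribund arrays, so the sizes of the genotype effects come from the 6 month 4 arrays. A further fit added the product of both genotypes. Adjusted p values are Benjamini-Hochberg values with a threshold of 0.05. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 29 lists with members tested, beside camera with an estimated correlation and fry. Camera compares a list with other genes. Fry asks whether the list itself moves. Fitted effects and their medians include values that were dim on some arrays and are no bounds. The medians given for pairs of arrays do hold such genes at their bound.

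Pairs of arrays were described by the number of genes at least 2-fold apart, among genes well above background on at least 1 of both arrays. A dim value was raised to the lowest signal well above background on its array, so the difference is a bound ("at least"). The 2 wild-type CD45.1 arrays gave the background count. The median of each list was ranked among 10000 random lists matched over 10 bins of brightness. Arrays came from 3 slides: WT, Double_mutant and Double_MDS on slide 1, Ezh2_deleted, RUNX1_mutant and both CD45.1 arrays on slide 2, and Double_MDS_ML on slide 3. Hence pairs among WT, Double_mutant and Double_MDS lie within a slide, as do pairs among Ezh2_deleted, RUNX1_mutant and both CD45.1 arrays, while the other pairs cross slides.

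The model, the pairs, the 30 gene lists (554 genes, 545 with a probe) and the rule for naming genes were fixed before the data were examined. For a tested effect the rule names the 8 largest increases and 8 largest decreases past the threshold, or the 5 genes of smallest p where none passes. For a pair it names the 6 largest increases and decreases among genes well above background on both arrays and the 3 brightest on 1 array alone. Clone and locus names are left out. For lists it names 2 to 4 members with the largest difference. Ezh2, Ezh1, Runx1 and Ptprc are always named. The lists are PRC2 subunits, PRC1 subunits, Polycomb-silenced developmental regulators, oncofetal and let-7 axis genes, CDK inhibitors, Hox A and B genes with Meis and Pbx, stem cell, lymphoid-primed progenitor, myeloid progenitor, neutrophil, monocyte and macrophage, erythroid, megakaryocyte and platelet, mast cell with basophil and eosinophil, B cell, T and NK cell, dendritic cell and MHC class II, and stromal and endothelial genes. The others are NF-kappaB, IL-6 with STAT3 and SOCS, TLR pathway, interferon-stimulated, immediate early, mitosis, DNA replication, p53 target, glycolysis and hypoxia, unfolded protein response, RUNX1 target and sex-linked control genes. Sex-linked genes were described, not tested as a list.

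Alternatives covered normexp background correction (offset 50), quantile normalization, the series table, 2 other filters on dim probes, the mean over the probes of a gene, an intensity trend in the variance, slide as a fixed or random block, month 4 arrays alone, no stage term, and leaving out each array. The scanner files hold no mean spot signal, so normexp used the median. A further 4 alternatives, named below, were chosen after seeing the data, as was slide as a block for the lists of the interaction. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. The fit was tested on simulated data with 13545 genes and 50 changed genes per size. At log2 changes of 1, 2, 4 and 6 it called 2%, 34%, 82% and 96% of them for Ezh2 deletion, 0%, 26%, 90% and 96% for RUNX1S291fs, and 0%, 8%, 78% and 96% for moribund stage. False calls numbered 8, 2 and 4. The simulated values had independent noise, exact additivity and no slide effect, so these shares hold for that setting alone.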

Results

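Gene expression was measured in LSK cells of transplanted mice on 8 arrays, 1 array for each of 8 groups, so no group has a replicate. WT, Ezh2_deleted, RUNX1_mutant and Double_mutant were CD45.2 donor cells taken at month 4, the last of them carrying both lesions. Double_MDS and Double_MDS_ML were CD45.2 cells of single moribund mice with both lesions. CD45.1_in_RUNX1_mutant and CD45.1_in_double_mutant were wild-type competitor cells that had shared the marrow of mutant cells. The share of probes well above background was 55.3% for WT, 50.7% for Ezh2_deleted, 48.2% for RUNX1_mutant, 52.1% for Double_mutant, 54.5% for Double_MDS, 49.99% for Double_MDS_ML, 43.9% for CD45.1_in_RUNX1_mutant and 49.9% for CD45.1_in_double_mutant. The 75th percentile of signal ran from 185.7 on the dim CD45.1_in_RUNX1_mutant array to 474.1 on the WT array. Levels are log2 signal relative to that percentile of the array, and effects and differences are log2 values, each gene read from 1 probe.

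The targeted genes come first. Ezh2, the histone H3 lysine methyltransferase of Polycomb repressive complex PRC2, gave 3.46 on WT, 3.51 on Ezh2_deleted, 3.40 on RUNX1_mutant, 3.42 on Double_mutant, 3.29 on Double_MDS, 3.10 on Double_MDS_ML, 4.01 on CD45.1_in_RUNX1_mutant and 3.85 on CD45.1_in_double_mutant, and the Ezh2 deletion effect on it was -0.15, SE 0.29, adjusted p = 1.00. Where its probe lies relative to the deleted exons is not given in the sources used here, and a probe outside the deleted part checks nothing, so the arrays neither show nor exclude the deletion. Runx1, a transcription factor needed to form blood stem cells, gave 3.04 on WT, 3.38 on Ezh2_deleted, 4.41 on RUNX1_mutant, 3.47 on Double_mutant, 5.31 on Double_MDS, 4.65 on Double_MDS_ML, 3.25 on CD45.1_in_RUNX1_mutant and 3.55 on CD45.1_in_double_mutant. Its RUNX1S291fs effect was 0.72, SE 0.37, adjusted p = 1.00, and its stage effect 1.20, SE 0.46, adjusted p = 0.30. Whether this probe reads the retroviral RUNX1S291fs is not given in the sources used here. Ezh1, the other methyltransferase of PRC2, lay between 3.45 and 4.77, and Ptprc, which encodes CD45, between 0.78 and 2.20.

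The Ezh2_deleted array was set against WT to ask what loss of Ezh2 alone does to stem and early progenitor cells. B cell genes were far higher: Igll1, part of the surrogate light chain, by 6.73, or 106-fold, Vpreb3 by 6.41 and Pou2af1, a co-activator in B cells, by 6.50. Neutrophil granule genes were higher too, with Ngp at 4.23, the lactoferrin gene Ltf at 4.19 and the cathelicidin gene Camp at 4.12. Cdkn2a, a cell cycle inhibitor locus that Polycomb complexes silence, was at least 5.97 higher. Lower on Ezh2_deleted were Vwf, the von Willebrand factor gene, at -2.63, Gp1ba, its platelet receptor, at -2.22, and the stem cell genes Slamf1 at -2.58 and Sult1a1 at -2.38.

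By list, the median difference from WT was 5.78 for B cell genes (11 of 12 at least 2-fold higher), 3.37 for neutrophil genes (13 of 16) and 1.11 for NF-kappaB genes (12 of 22, Il1b 2.95). Smaller were 0.90 for immediate early genes (6 of 17, Nr4a1 2.48), 0.56 for p53 targets (6 of 16, Cdkn1a 2.66) and 0.70 for CDK inhibitors (3 of 7). It was -1.12 for megakaryocyte genes (9 of 17 at least 2-fold lower) and -0.60 for stem cell genes (10 of 27). Oncofetal genes had a median of 0.05, with Hmga2, a chromatin protein of fetal stem cells, at 2.32 and Igf2bp3, an RNA-binding protein of fetal tissue, at least 2.70 higher. Of the remaining largest differences, Fxyd6 was 6.52, Gfra2 6.51 and Cd83, a marker of activated antigen-presenting cells, 6.4, against Phldb2 -3.54, Atp8b5 -3.08, Gstm2 -2.87, H2ac6 -2.80, Rap1gap -2.72 and Hoxb2 -2.68. Well above background on Ezh2_deleted but not on WT were the Y-linked Eif2s3y (at least 240.3-fold) and Ddx3y (at least 123-fold) and the dendritic cell receptor gene Xcr1 (at least 71.5-fold). On WT but not Ezh2_deleted were Xist, the RNA that silences an X chromosome (at least 49.4-fold), Syt10 (at least 44.6-fold) and Hoxc6 (at least 17.2-fold). By the Y-linked genes and Xist both arrays differ in the sex of their cells. This pair cannot tell sex apart from Ezh2 deletion.

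The pair gave 1100 genes at least 2-fold higher and 538 at least 2-fold lower among 14089 genes measured. Pairs of wild-type arrays gave 2139 genes at least 2-fold apart between both wild-type CD45.1 arrays, 2489 between CD45.1_in_RUNX1_mutant and WT and 924 between CD45.1_in_double_mutant and WT, the first 2 of these with the dimmest array. The pair crosses slides. On its own slide, Ezh2_deleted exceeded CD45.1_in_RUNX1_mutant and CD45.1_in_double_mutant by list medians of 4.92 and 2.18 for B cell genes, 0.98 and 2.88 for neutrophil genes and 0.77 and 0.46 for CDK inhibitors. Megakaryocyte genes there gave 0.71 and -1.24, stem cell genes 0.56 and -0.79, and immediate early genes -0.17 and -1.05.

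In the fit over all 8 arrays, the Ezh2 deletion effect averages the changes on Ezh2_deleted and Double_mutant. Both moribund arrays, fitted by the stage term, add to the spread alone. CDK inhibitors were higher as a list (adjusted p = 0.597 with an estimated correlation), carried by Cdkn2a at 5.52, SE 0.85, and Cdkn2b, its neighbour with a similar role, at 2.12, SE 0.61, each short of the threshold over all genes. These sizes are no bounds, as among the 4 undeleted arrays Cdkn2a was well above background on 1 and Cdkn2b on 0. B cell genes were positive in 10 of 10, led by Igll1 at 4.32, SE 1.40, but this rested largely on 1 array: their mean level was 3.88 on Ezh2_deleted and -2.03, -2.94 and -1.79 on Double_mutant, Double_MDS and Double_MDS_ML, against -0.94 on WT. Neutrophil genes were positive in 14 of 16, led by Stfa1 at 3.77, SE 2.28. Immediate early genes, the first transcripts to answer a stimulus, were negative in 17 of 17, with Fosb at -1.92, Egr2 at -1.82 and Klf2 at -1.78. This rested largely on Double_mutant (mean level 3.60) against RUNX1_mutant (6.34), a pair across slides. The mean was 4.75 on Ezh2_deleted, against 4.09 on WT, 4.91 on CD45.1_in_RUNX1_mutant and 5.66 on CD45.1_in_double_mutant. PRC2 subunits, Polycomb-silenced developmental regulators and Hox genes gave medians of -0.15, -0.14 and -0.15, with adjusted p = 0.659, 0.977 and 0.980, and PRC1 and oncofetal genes -0.28 and 0.12, with adjusted p = 0.0736 and 0.305.

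In limma, 0 of 13545 genes passed for this effect, 321 had an unadjusted p under 0.05 (677 expected by chance), and every alternative that ran gave 0. Smallest in p were Gcsam, a germinal centre gene, at 2.31, SE 0.30, Slc37a2 at 2.19, SE 0.32, Elovl2, a fatty acid elongase, at 2.33, SE 0.35, Bex2 at 3.09, SE 0.47 and Rap1gap, a brake on the small GTPase Rap, at -2.45, SE 0.38, each with adjusted p = 0.695. Elovl2 was well above background on 3 of 8 arrays, Slc37a2 on 5 and Gcsam on 6, so their sizes rest partly on dim values. By camera 8 of 29 lists passed, 5 higher and 3 lower, against 0 with an estimated correlation and 0 by fry. Higher were CDK inhibitors (median 0.27, adjusted p = 0.000189) and B cell genes (median 2.75, adjusted p = 3.77e-11). For CDK inhibitors and B cell genes, in that order, adjusted p = 0.597 and 0.597 with an estimated correlation, 4.30e-05 and 4.55e-15 with slide as a block, and 8.75e-07 to 0.994 and 5.24e-18 to 0.994 over the alternatives. Neutrophil (median 3.17, adjusted p = 3.07e-07) and mitosis genes (median 0.29, adjusted p = 0.000193, 20 of 20 positive, Cenpa 0.80 and Aurkb 0.68) were higher. The latter rested largely on Double_mutant (mean level 4.22) against RUNX1_mutant (3.09), Ezh2_deleted (3.53) lying within the wild-type range (3.29 to 4.01). For neutrophil and mitosis genes, in that order, adjusted p = 0.664 and 0.664 with an estimated correlation, 1.11e-15 and 0.00108 with slide as a block, and 3.60e-16 to 0.994 and 2.25e-07 to 0.994 over the alternatives. Lymphoid-primed progenitor genes were higher (median 0.16, adjusted p = 0.0159; 11 of 15 positive, the homing receptor Ccr9 1.68 and the recombinase Rag1 1.48). For lymphoid-primed genes, adjusted p = 0.664 with an estimated correlation, 0.0133 with slide as a block, and 0.000496 to 0.994 over the alternatives. Immediate early (median -1.18, adjusted p = 4.80e-09) and stem cell genes (median -0.34, adjusted p = 0.0207; 8 of 28 positive, Prdm16, a stem cell regulator, -2.15 and Sult1a1 -2.08) were lower. For immediate early and stem cell genes, in that order, adjusted p = 0.664 and 0.782 with an estimated correlation, 1.07e-12 and 0.00994 with slide as a block, and 2.18e-13 to 0.994 and 2.31e-08 to 0.994 over the alternatives. Megakaryocyte genes were lower (median -0.44, adjusted p = 0.0377; 3 of 17 positive, Vwf -1.15 and the integrin gene Itga2b -1.05). For megakaryocyte genes, adjusted p = 0.782 with an estimated correlation, 0.00686 with slide as a block, and 1.92e-08 to 0.994 over the alternatives. Adjusted over the list alone, 2 CDK inhibitors (Cdkn2a and Cdkn2b), 0 B cell genes and 0 neutrophil genes passed.

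The other 21 lists had adjusted p = 0.0615 (erythroid) to 0.980 (NF-kappaB), and with slide as a block erythroid genes (0.0133; 0.0133 to 0.994 over the alternatives) and p53 targets (0.00930; 0.000140 to 0.994) passed. The median, mean and test differed in sign for Hox, interferon-stimulated and unfolded protein response genes. Without the Ezh2_deleted array the B cell (0.694), CDK inhibitor (0.680) and lymphoid-primed calls (0.870) ended, the last also without CD45.1_in_RUNX1_mutant (0.162), and without RUNX1_mutant or Double_mutant those of stem cell (0.869), immediate early (0.869) and mitosis genes (0.864) did. Stem cell genes also lost the call without WT (0.186) or CD45.1_in_double_mutant (0.233), and megakaryocyte genes without WT (0.357), Ezh2_deleted (0.251), RUNX1_mutant or Double_mutant (0.285), either moribund array (0.0504) or CD45.1_in_double_mutant (0.261). Without the stage term the lymphoid-primed (0.277), mitosis (0.559) and megakaryocyte calls (0.0501) ended, leaving 5 of the 8. With genes well above background on all 8 arrays those of CDK inhibitors (0.152) and megakaryocyte genes (0.114) did, leaving 6, and on month 4 arrays that of megakaryocyte genes (0.0504).

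The RUNX1_mutant array was set against WT to ask what the truncated RUNX1S291fs does on its own. Mast cell and basophil genes were higher, among them Cpa3, a mast cell protease, by 5.30, Hdc, the enzyme that makes histamine, by 3.47, and the chymase gene Cma1, at least 5.05 higher. Immediate early genes were higher by 4.16 for Atf3, 3.75 for Egr2 and 3.38 for Fosb. Also higher were Cd14, the lipopolysaccharide co-receptor, by 6.29 or 78.2-fold, and the chemokines Ccl2 by 5.41 and Cxcl2 by 4.21. Lower were Il7r, the interleukin-7 receptor, at -3.59, Dntt, which adds bases to antigen receptor genes, at -2.83 and Blnk, a B cell adaptor, at -2.99.

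The list medians against WT were 2.31 for mast cell genes (14 of 14 at least 2-fold higher), 2.23 for immediate early genes (16 of 18) and 1.86 for neutrophil genes (11 of 14, Lcn2 2.68). Next came 1.05 for NF-kappaB genes (12 of 23), 0.86 for megakaryocyte genes (8 of 17, the platelet receptor Clec1b 3.11 and Treml1 2.72) and 0.85 for unfolded protein response genes (6 of 18). They were -1.0 for lymphoid-primed genes (7 of 15 at least 2-fold lower), -0.84 for B cell genes (5 of 10) and -0.58 for interferon-stimulated genes (6 of 26, Oasl2 -2.67). Further large differences were those of Hspa1a, a heat shock protein, at 6.04, Id3, an inhibitor of E proteins, at 5.26 and Jchain, which joins immunoglobulin units, at 4.98. At the other end lay Bdh2 -4.90, Hnf4a -4.77, Rps4l -4.33, Bex1 -4.31, Arhgef25 -4.31 and Ube2e2 -4.23. The mast cell protease gene Mcpt4 (at least 229.6-fold), Ttc29 (at least 41.4-fold) and Olfr213 (at least 36.2-fold) were well above background on RUNX1_mutant but not WT, and Syt10 (at least 40.9-fold), the interleukin-18 receptor gene Il18r1 (at least 24.5-fold) and Epdr1 (at least 23.2-fold) the reverse.

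In all the pair gave 1197 genes at least 2-fold higher and 805 at least 2-fold lower (59.8% higher, or 49.2% with measured values in place of the bound), against 2139 between both wild-type CD45.1 arrays and 924 between CD45.1_in_double_mutant and WT. Within the slide, RUNX1_mutant minus CD45.1_in_RUNX1_mutant and minus CD45.1_in_double_mutant gave medians of 1.23 and 2.60 for mast cell genes, 2.67 and 0.77 for megakaryocyte genes, 1.5 and 0.75 for immediate early genes, -0.42 and -0.79 for lymphoid-primed genes and -1.58 and -3.85 for B cell genes. T and NK cell genes gave -1.10 and 0.45, neutrophil genes -0.49 and 2.18, unfolded protein response genes -0.50 and 0.10, interferon-stimulated genes 0.24 and -0.18 and myeloid progenitor genes -1.22 and -0.04.

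Of the 4 RUNX1S291fs carriers the stage term takes up the mean of both moribund ones. The RUNX1S291fs effect thus averages the changes on RUNX1_mutant and Double_mutant, shared or not. Tmprss4, a membrane serine protease, was at least 6.59-fold lower on average on the carriers, being well above background on each of the 4 other arrays and 0 of 4 carriers. Il18r1 was lower on each carrier than on each other array, being well above background on 3 of 4 carriers. Lymphoid-primed, B cell, T and NK cell and dendritic cell genes were lower as lists, and mast cell, megakaryocyte and myeloid progenitor genes higher (adjusted p = 0.360 to 0.619 with an estimated correlation). Among single genes, Rag1 had an effect of -5.32, SE 1.23, the T cell kinase Lck -3.12, SE 0.50, Igll1 -6.09, SE 1.40, Cpa3 4.73, SE 0.51 and Clec1b 3.65, SE 0.56, each short of the threshold over all genes. B cell sizes, here and below, rested largely on Ezh2_deleted (mean level 3.88). Wild-type arrays lay at -1.07 to 1.57, RUNX1_mutant at -2.40 and Double_mutant at -2.03. The fitted effects were -5.0, SE 0.38, for Tmprss4 and -4.61, SE 0.39, for Il18r1, each with adjusted p = 0.0412 in limma. Only these 2 passed, 807 having an unadjusted p under 0.05. With slide or the kind of recipient as a block 0 passed. With slide both genes had adjusted p = 0.178 (0.00818 to 0.490 for Tmprss4 and 0.0395 to 0.490 for Il18r1 over the alternatives). Without WT, Ezh2_deleted, RUNX1_mutant, Double_mutant or CD45.1_in_double_mutant the count was 0, without Double_MDS or Double_MDS_ML 4, and without CD45.1_in_RUNX1_mutant 10.

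By camera 13 of 29 lists passed for RUNX1S291fs, 7 higher and 6 lower, against 0 with an estimated correlation and 0 by fry. Lower were lymphoid-primed (median -0.72, adjusted p = 2.09e-06, 13 of 15 negative, Rag1, Il7r -3.36, Dntt -2.33) and B cell genes (median -4.22, adjusted p = 2.21e-09, 9 of 10 negative, Vpreb3 -5.35, Vpreb1 -4.87, Ebf1 -4.45). For lymphoid-primed and B cell genes, in that order, adjusted p = 0.360 and 0.360 with an estimated correlation, 2.74e-06 and 2.36e-09 with slide as a block, and 2.85e-09 to 0.360 and 1.69e-13 to 0.385 over the alternatives. T and NK cell (median -1.16, adjusted p = 3.28e-05; Lck, and Tcf7, a factor of early T cells, -2.34) and dendritic cell genes (median -0.93, adjusted p = 0.000250; Ly6d -2.61, H2-Aa -2.26, the cytokine receptor Flt3 -1.84) were lower. For T and NK cell and dendritic cell genes, in that order, adjusted p = 0.360 and 0.360 with an estimated correlation, 2.01e-05 and 4.06e-05 with slide as a block, and 1.41e-06 to 0.385 and 9.82e-07 to 0.519 over the alternatives. Interferon-stimulated (median -0.38, adjusted p = 0.00259; Ifi27l2a -2.05, Oasl2 -1.83) and DNA replication genes (median -0.25, adjusted p = 0.00236; the cyclin Ccne2 -1.60, Cdc45 -0.73) were lower. For interferon-stimulated and DNA replication genes, in that order, adjusted p = 0.587 and 0.619 with an estimated correlation, 0.00139 and 0.00308 with slide as a block, and 9.61e-05 to 0.688 and 2.73e-05 to 0.688 over the alternatives. Adjusted over the list alone, 5 lymphoid-primed, 6 B cell and 3 T and NK cell genes passed, each of them lower.

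Higher were mast cell (median 2.44, adjusted p = 4.99e-09; 13 of 14 positive, Cma1 4.97, Cpa3, Ms4a2 of the IgE receptor 4.21) and megakaryocyte genes (median 1.12, adjusted p = 8.97e-09; 17 of 17 positive, Treml1 3.53, the chemokine Ppbp 3.28, Itga2b 2.87), with 4 members of each passing higher when adjusted over the list alone. For mast cell and megakaryocyte genes, in that order, adjusted p = 0.360 and 0.360 with an estimated correlation, 4.40e-13 and 6.79e-07 with slide as a block, and 1.05e-13 to 0.385 and 8.20e-12 to 0.419 over the alternatives. Myeloid progenitor (median 0.97, adjusted p = 0.00236; 17 of 18 positive, the granulocyte factor Cebpe 2.55, Ms4a3 2.54, with Nkg7 at -2.59) and neutrophil genes (median 1.25, adjusted p = 0.0273; Chil3 2.38, Stfa1 2.08) were higher. For myeloid progenitor and neutrophil genes, in that order, adjusted p = 0.619 and 0.696 with an estimated correlation, 0.00839 and 0.000138 with slide as a block, and 1.54e-07 to 0.688 and 0.000138 to 0.775 over the alternatives. Monocyte (median 0.87, adjusted p = 0.0152; Cd14 3.55, the macrophage marker Adgre1 3.37) and TLR pathway genes (median 0.55, adjusted p = 0.00140; Cd14, Tlr1 2.22) were higher. For monocyte and TLR pathway genes, in that order, adjusted p = 0.587 and 0.360 with an estimated correlation, 0.0114 and 0.00105 with slide as a block, and 0.000722 to 0.688 and 0.000172 to 0.419 over the alternatives. IL-6 and STAT3 genes were higher (median 0.32, adjusted p = 0.00283; 15 of 15 positive, Cebpd 1.56). For IL-6 and STAT3 genes, adjusted p = 0.360 with an estimated correlation, 0.00104 with slide as a block, and 0.000823 to 0.526 over the alternatives. RUNX1 targets of textbooks gave a median of 0.31, adjusted p = 0.131, and stem cell genes 0.60, adjusted p = 0.327.

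The other 16 lists had adjusted p = 0.0632 (unfolded protein response) to 0.978 (PRC2 subunits), and with slide as a block immediate early (2.94e-06; 7.79e-07 to 0.872 over the alternatives) and unfolded protein response genes (0.0150; 0.00955 to 0.745) passed. PRC2 subunits and CDK inhibitors differed in sign between median, mean and test. Without Ezh2_deleted or Double_mutant the calls of T and NK cell (0.164), interferon-stimulated (0.653), myeloid progenitor (0.687), neutrophil (0.0815), monocyte (0.538) and TLR pathway genes (0.193) ended. Without RUNX1_mutant those of neutrophil (0.303), IL-6 and STAT3 (0.526) and DNA replication genes (0.542) did, and without WT that of neutrophil genes (0.0603). Without the stage term the monocyte (0.209), myeloid progenitor (0.571), neutrophil (0.572) and TLR pathway calls (0.230) ended, leaving 9 of the 13. With genes well above background on all 8 arrays that of monocyte genes (0.0888) did.

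**Figure D1:**
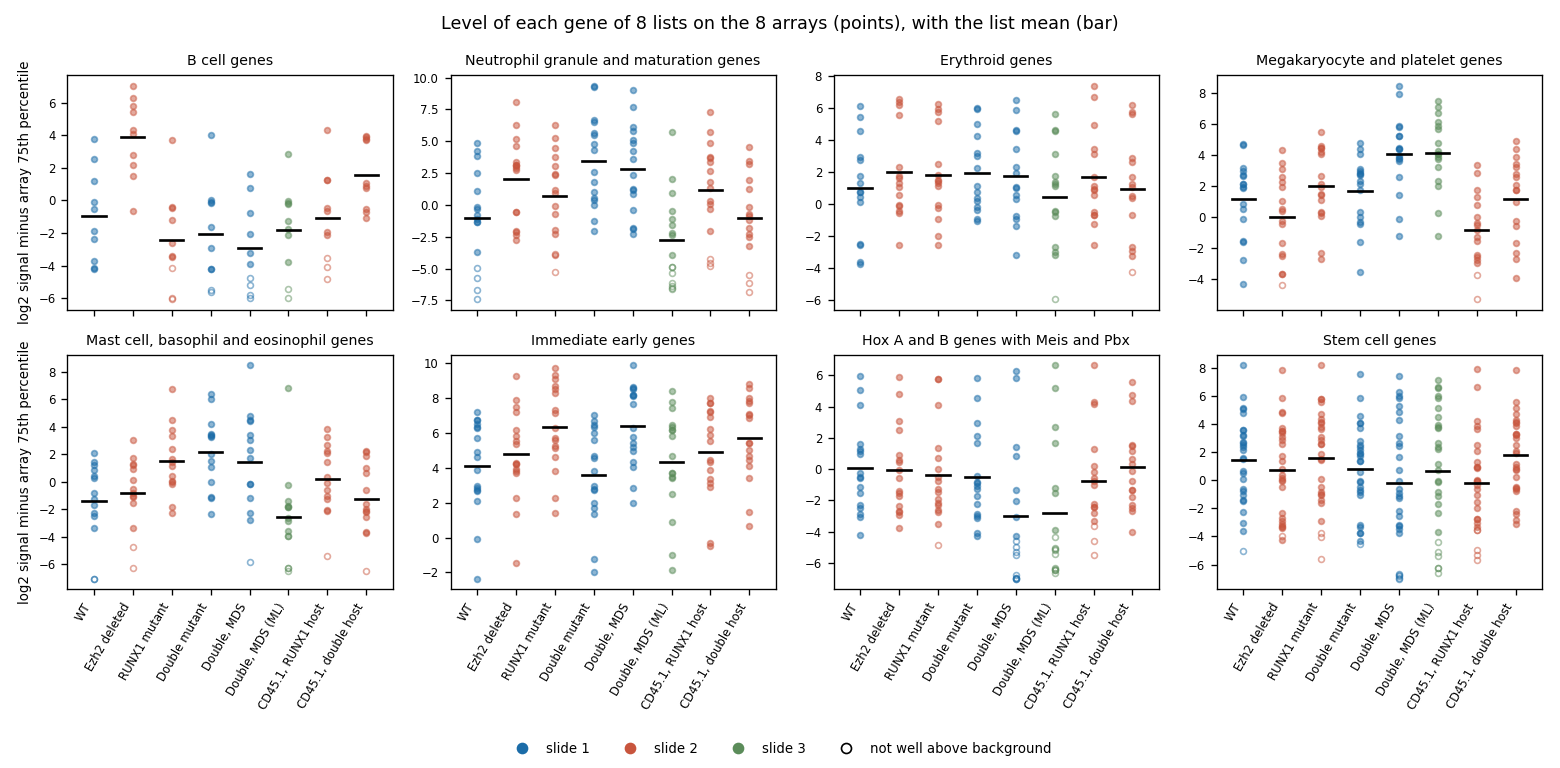
Level of each gene (points, log2 signal minus the 75th percentile of the array) of 8 gene lists on the 8 arrays (x axis), coloured by slide, with the list mean as a bar and open points for genes not well above background. B cell genes averaged 3.88 on Ezh2_deleted, Hox genes -3.02 and -2.80 on the moribund arrays, and megakaryocyte genes 4.12 and 4.15 there.

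Double_mutant was compared with WT, RUNX1_mutant and Ezh2_deleted to ask what the lesions do together before disease. Of its differences from WT, on the same slide, Lrg1, a glycoprotein of maturing neutrophils, was higher by 8.5 or 362-fold, the calprotectin gene S100a8 by 6.70, the neutrophil elastase gene Elane by 5.99 and Cebpe by 5.72. Monocyte genes Cd14 (6.65) and F13a1 (5.91) and mast cell genes Hdc (5.70), the tryptase Tpsb2 (5.06) and Cpa3 (4.94) were higher as well. Of fetal genes, Igf2bp3 was at least 5.11 higher and Dlk1, a Notch pathway ligand, 3.39. Lower were Lck at -3.67, Il7r at -2.65, Flt3 at -2.47 and the Hox genes Hoxa10 at -3.72 and Hoxb2 at -2.99.

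In Double_mutant minus WT the median was 4.83 for neutrophil genes (14 of 16 at least 2-fold higher), 2.34 for mast cell genes (14 of 15), 2.06 for monocyte genes (8 of 14) and 1.75 for myeloid progenitor genes (13 of 18). Smaller were the medians 1.35 for unfolded protein response genes (11 of 18, Sdf2l1 2.66), 1.03 for oncofetal genes (5 of 10) and 1.02 for mitosis genes (10 of 20, the mitotic kinase Plk1 1.53). It was -1.04 for T and NK cell genes (6 of 12 at least 2-fold lower), -0.97 for lymphoid-primed genes (6 of 15), -0.91 for interferon-stimulated genes (11 of 26, Oas2 -2.91), -0.63 for stem cell genes (10 of 28), -0.59 for Hox genes (7 of 17) and -0.49 for immediate early genes (4 of 17, Junb -1.16). Cdkn2a was at least 4.27 higher. The other genes furthest up were Wfdc21 (7.82), Hsd11b1 (6.90), the siderophore-binding Lcn2 (6.88), Dmkn (6.86) and Mogat2 (6.82), and furthest down Bdh2 (-5.46), the chemokine receptor Ccr7 (-4.65), Klhl30 (-4.34), Hnf4a (-4.25), Rbpms2 (-4.14) and C1ra (-4.13). The mast cell protease genes Mcpt4 (at least 276-fold), Tpsg1 (at least 206-fold) and Cma1 (at least 151-fold) were well above background on Double_mutant alone of the pair, and Syt10 (at least 63.3-fold), Lrrc66 (at least 31.2-fold) and Dcaf12l1 (at least 22.8-fold) on WT alone. In all, 1494 genes at least 2-fold higher and 1117 at least 2-fold lower were counted, against 2139 genes between both wild-type CD45.1 arrays, 2489 between CD45.1_in_RUNX1_mutant and WT and 924 between CD45.1_in_double_mutant and WT.

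Adding Ezh2 deletion to RUNX1S291fs, read as Double_mutant minus RUNX1_mutant crosses slides. Prom1, a membrane protein of progenitors, was higher by 7.14 or 141-fold, S100a8 by 4.76, Elane by 4.38 and Igf2bp3 was at least 3.97 higher. Fosb (-4.46), Atf3 (-4.90), Cxcl2 (-3.66) and Hspa1a (-6.20) were lower. List medians were 2.92 for neutrophil genes (14 of 16 at least 2-fold higher), 1.54 for myeloid progenitor genes (13 of 18), 1.11 for mitosis genes (14 of 20, Aurkb 2.36) and 0.94 for oncofetal genes. They were -2.68 for immediate early genes (16 of 18 at least 2-fold lower), -1.76 for NF-kappaB genes (16 of 23) and -0.78 for stem cell genes (11 of 28, Procr, the protein C receptor, -2.45). Mogat2 (6.83), Wfdc21 (6.16), Afap1 (5.74), Hsd11b1 (5.73) and Lrg1 (5.40) were also among the furthest up, and Id3 (-5.77) and Tnfrsf12a (-4.44) among the furthest down. On Double_mutant alone stood Rhou (at least 43.1-fold), Gpx3 (at least 39.8-fold) and Chst13 (at least 28.2-fold), and on RUNX1_mutant alone Egr4 (at least 57.1-fold), Cadps2 (at least 42.0-fold) and Ttc29 (at least 29.0-fold). The counts were 1104 genes at least 2-fold higher and 1157 at least 2-fold lower (48.8% higher, or 55.8% with normexp correction and 54.3% with measured values in place of the bound).

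Adding RUNX1S291fs to Ezh2 deletion, read as Double_mutant minus Ezh2_deleted across slides, gave the highest count of the month 4 pairs compared, 1521 genes at least 2-fold higher and 1536 at least 2-fold lower (49.8% higher, or 56.5% with normexp correction). B cell genes lay far lower, with Igll1 at -8.55, Vpreb3 at -7.98, Vpreb1 at -7.23, Pou2af1 at -7.01 and Vpreb2 at -6.98, a list median of -6.50 (11 of 12 at least 2-fold lower). T and NK cell genes (-1.85; Lck -3.95), dendritic cell genes (-1.65; Ly6d -4.37), NF-kappaB genes (-1.56; Cd83 -5.49, Tnf -3.60) and lymphoid-primed genes (-1.47; Il7r -3.54) were lower too, and Hoxa10 was -5.18. Higher were myeloid progenitor genes (2.67; Ms4a3 6.67, Elane 5.88), mast cell genes (2.28; Tpsb2 4.91), megakaryocyte genes (2.02; Treml1 3.36) and oncofetal genes (0.93; Dlk1 3.91). Dmkn (7.75), the complement gene C4b (6.73), F13a1 (6.31), Igsf6 (6.21) and Cldn15 (6.19) completed the furthest up, and Gfra2 (-6.75) the furthest down. Mcpt4 (at least 148-fold), Tpsg1 (at least 111-fold) and Cma1 (at least 81.3-fold) were on Double_mutant alone, and Eif2s3y (at least 168-fold) and Ddx3y (at least 85.8-fold) on Ezh2_deleted alone. By these Y-linked genes this pair, too, differs in the sex of its cells.

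Whether Ezh2 deletion acts differently beside RUNX1S291fs was asked by the interaction of both genotypes. At month 4 it sets WT and Double_mutant, on slide 1, against Ezh2_deleted and RUNX1_mutant, on slide 2, so it runs along slide and rests on the CD45.1 arrays to tell them apart. Myeloid progenitor genes had the more positive Ezh2 effect with RUNX1S291fs (adjusted p = 0.685 with an estimated correlation, as for the lists that follow), 17 of 18 being positive, with Ms4a3 at 6.89, SE 2.52, and Elane at 6.42. Immediate early and NF-kappaB genes had the more negative one, 15 of 17 and 19 of 22 being negative, with Nr4a1 at -4.82, Cd83 at -7.53 and Cxcl2 at -4.97. B cell genes were negative in 9 of 10. In limma 0 genes passed, 886 had an unadjusted p under 0.05, and every alternative that ran gave 0. Smallest in p were Plekha7 (-6.52, SE 0.65), Prkcz, an atypical protein kinase C (-6.37, SE 0.69), Tex28 (-5.66, SE 0.65), the ammonium transporter Rhcg (4.39, SE 0.59) and Mst1 (4.68, SE 0.63), with adjusted p = 0.467 to 0.661. Their sizes rest on dim values, since Plekha7, Prkcz and Tex28 were not well above background on Double_mutant, nor Rhcg and Mst1 on Ezh2_deleted and RUNX1_mutant. By camera 9 of 29 lists passed, 3 higher and 6 lower, each with adjusted p = 0.685 with an estimated correlation, and 0 passed by fry. With slide as a block, a repeat added after the results were seen that has 1 residual degree of freedom, the 9 had the same sign and adjusted p = 1.06e-10 to 0.0273, and 17 lists passed. The median, mean and test differed in sign for Polycomb-silenced, neutrophil, megakaryocyte, mast cell and stromal genes. The term could not be fitted without Ezh2_deleted, RUNX1_mutant or Double_mutant, since each is the single array of its genotype at month 4.

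**Figure D2:**
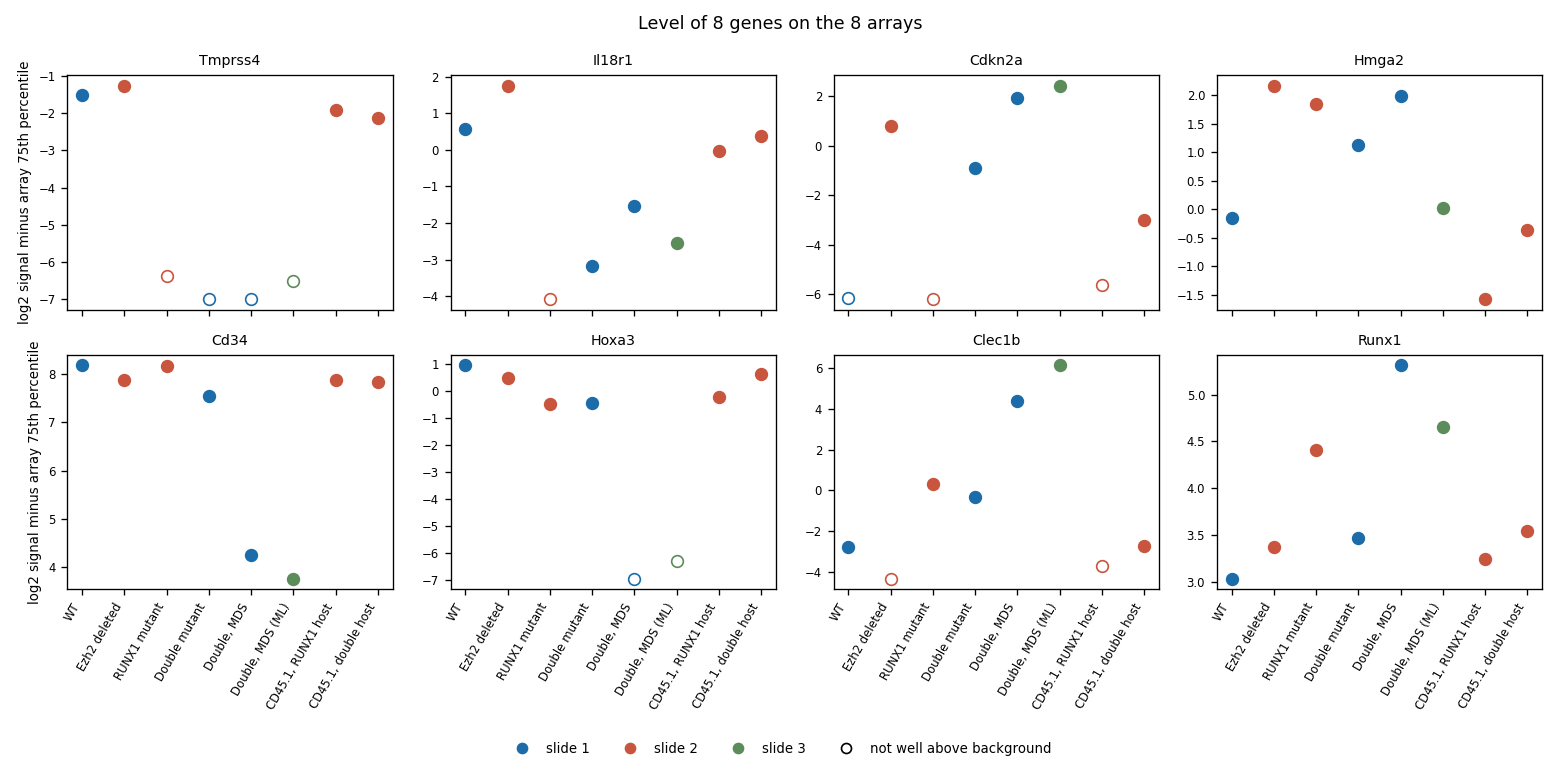
Level (log2 signal minus the 75th percentile of the array) of 8 genes on the 8 arrays (x axis), 1 point per array, coloured by slide, with open points for values not well above background. Tmprss4 is open on the 4 RUNX1S291fs arrays, and Cd34 lies at 4.25 and 3.76 on the moribund arrays against 7.54 to 8.18 on the others.

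The moribund stage effect asked how double-mutant cells in disease differ from those at month 4. Of 17 Hox list genes, which mark stem and progenitor identity, 7 passed, each lower (as a list adjusted p = 3.53e-07, and adjusted p = 0.576 with an estimated correlation). Hoxa3 was at least 16.6-fold lower and Hoxb5 at least 12.5-fold lower on the moribund arrays than on Double_mutant, and Hoxa5 had an effect of -4.77. Procr fell by 5.85 (57.6-fold by the fit, 31.0-fold between Double_mutant and the mean of both moribund arrays), Cd34 by 3.70 and Ly6a, which encodes the sort marker Sca-1, by 2.26, while Kit gave 0.61, adjusted p = 0.619 (Ly6a and Kit were singled out after their values were seen). Stem cell genes as a list gave a median of -0.25, adjusted p = 0.369. Fbp1, a gluconeogenic enzyme, fell by 7.92 (242-fold by the fit, 447-fold against Double_mutant) and the cytokine receptor Flt3 by 5.46. Of 17 megakaryocyte genes 2 passed, Clec1b, higher by 5.80 (55.7-fold by the fit, 49.1-fold against Double_mutant), and the collagen receptor Gp6, by 4.13 (as a list adjusted p = 3.47e-11, and adjusted p = 0.576 with an estimated correlation).

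In limma 250 genes passed, 37 higher and 213 lower, and 1857 had an unadjusted p under 0.05. Folds given as at least are bounds on the difference between Double_mutant and the mean of both moribund arrays, and other folds are those of the fitted effect. Furthest up were Tnni1, a slow muscle troponin, at 6.92, SE 0.78 (at least 125-fold, adjusted p = 0.0132), Clec1b at 5.80, SE 0.69 (adjusted p = 0.0154) and Sox6, a transcription factor of erythroid cells, at 5.50, SE 0.70 (at least 39.5-fold, adjusted p = 0.0162). Next came Tmbim7 at 5.23 (at least 7.98-fold), Glod5 at 4.74 (26.7-fold), Adamtsl1 at 4.50 (22.6-fold), Tmie at 4.48 (at least 5.51-fold) and Slc4a11 at 4.47 (22.1-fold). Furthest down were Fbp1 at -7.92, SE 0.79 (adjusted p = 0.0115), the transporter gene Slc16a11 at -6.22, SE 0.63 (74.5-fold) and Hoxa3 at -6.20, SE 0.50 (adjusted p = 0.00850). They were followed by Raet1e, a ligand of the receptor NKG2D, at -6.13 (at least 13.2-fold), Procr at -5.85, SE 0.95 (adjusted p = 0.0327), C2cd4b at -5.70 (at least 17.2-fold), Arhgap32 at -5.58 (at least 9.48-fold) and Hoxb5 at -5.54, SE 0.88 (adjusted p = 0.0311). Normexp correction gave 80 higher and 210 lower, 160 of these 290 shared with the 250, and slide as a block 8 higher and 67 lower, 35 of the 75 shared. As Double_MDS_ML is the only array on slide 3, that block takes it out of the stage effect, which then rests on Double_MDS alone, here and for the lists below. Of the 16 genes at either end, Tnni1, Fbp1, Hoxa3 and C2cd4b passed in that fit, the 16 having adjusted p = 0.0466 to 0.168 there and 0.00257 to 0.358 over the alternatives. With the kind of recipient as a block, added after the results were seen and leaving 2 residual degrees of freedom, 0 genes passed (smallest adjusted p = 0.177). That block leaves the moribund mice unmarked, so for stage it is no adjustment. Leaving out Double_mutant gave 0 genes, WT 70, CD45.1_in_double_mutant 81, Double_MDS 157 and Double_MDS_ML 381.

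By camera 13 of 29 lists passed for stage, 3 higher and 10 lower, against 0 with an estimated correlation and 2 by fry (Hox and stromal genes), with 10 by fry's test for change in either direction. Lower were Hox (median -2.02, adjusted p = 3.53e-07; 14 of 17 negative) and dendritic cell genes (median -1.61, adjusted p = 0.000485; 11 of 12 negative, Flt3 -5.46, H2-DMa -3.36), of which 7 and 2 passed over all genes, and 10 and 4 when adjusted over the list alone. For Hox and dendritic cell genes, in that order, adjusted p = 0.576 and 0.576 with an estimated correlation, 1.84e-05 and 2.10e-05 with slide as a block, and 1.82e-08 to 0.576 and 1.18e-05 to 0.576 over the alternatives. Hoxb4, singled out after its values were seen, lay between 1.41 and 1.67 on WT, Double_mutant and both moribund arrays. Myeloid progenitor (median -2.33, adjusted p = 0.000134; the repressor Gfi1 -5.60, Elane -4.65) and TLR pathway genes (median -0.99, adjusted p = 0.00674; Tlr4, the endotoxin receptor, -5.07) were lower. For myeloid progenitor and TLR pathway genes, in that order, adjusted p = 0.609 and 0.576 with an estimated correlation, 0.00816 and 0.00550 with slide as a block, and 1.41e-07 to 0.609 and 0.000586 to 0.576 over the alternatives. Neutrophil (median -3.80, adjusted p = 0.00995; Ltf -5.19, S100a8 -5.13) and mast cell genes (median -2.22, adjusted p = 0.00995; Tpsb2 -4.08, Cma1 -5.66, Hdc -5.21) were lower. The call ended with slide as a block, where Double_MDS alone carries the effect, and Double_MDS minus Double_mutant had medians of -0.30 and -0.19. For neutrophil and mast cell genes, in that order, adjusted p = 0.609 and 0.609 with an estimated correlation, 0.873 and 0.946 with slide as a block, and 1.19e-11 to 0.998 and 9.12e-10 to 0.965 over the alternatives. Mitosis (median -1.09, adjusted p = 5.27e-05; 20 of 20 negative, the spindle checkpoint genes Bub1 -1.67 and Bub1b -1.59) and DNA replication genes (median -0.69, adjusted p = 0.00820; Ccne2 -2.25) were lower. For mitosis and DNA replication genes, in that order, adjusted p = 0.609 and 0.609 with an estimated correlation, 0.0221 and 0.00152 with slide as a block, and 3.70e-07 to 0.609 and 0.000693 to 0.609 over the alternatives. Glycolysis (median -0.87, adjusted p = 0.00949; Vegfa -3.65, hexokinase Hk2 -2.28) and stromal genes (median -0.90, adjusted p = 0.0359; the matrix gene Sparc -3.86, Emcn -5.52) were lower. For glycolysis and stromal genes, in that order, adjusted p = 0.609 and 0.576 with an estimated correlation, 0.0308 and 0.180 with slide as a block, and 0.000693 to 0.609 and 0.0192 to 0.576 over the alternatives.

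Higher were megakaryocyte (median 2.14, adjusted p = 3.47e-11; 16 of 17 positive, Ppbp 4.36, Gp6 4.13, Gp5 3.68; 2 past over all genes and 9 adjusted over the list alone) and immediate early genes (median 1.27, adjusted p = 0.000581; 15 of 17 positive, Fosb 2.31, Egr2 1.70). For megakaryocyte and immediate early genes, in that order, adjusted p = 0.576 and 0.609 with an estimated correlation, 6.45e-08 and 4.48e-15 with slide as a block, and 1.24e-17 to 0.576 and 4.48e-15 to 0.609 over the alternatives. The p53 targets were higher (median 0.73, adjusted p = 0.0315; 12 of 16 positive, Phlda3 2.31, with Plk2 at -4.37). For p53 targets, adjusted p = 0.576 with an estimated correlation, 0.00157 with slide as a block, and 0.00157 to 0.930 over the alternatives. Of stem cell genes 3 fell over all genes and 7 passed adjusted over the list alone, 1 of them higher. Lymphoid-primed genes gave -0.86, adjusted p = 0.0955, with Flt3 and Lsp1 lower over all genes, CDK inhibitors 0.59, adjusted p = 0.124, and B cell genes -1.78, adjusted p = 0.196. Il6ra, the interleukin-6 receptor, fell by 4.14 (adjusted p = 0.0169) and Gbp3, an interferon-induced GTPase, by 2.93 (adjusted p = 0.0413). With slide as a block CDK inhibitors (0.0142; 0.0142 to 0.930 over the alternatives), NF-kappaB (0.000698; 4.19e-05 to 0.975) and interferon-stimulated genes (0.0313; 0.00499 to 0.845) passed, which is a statement on Double_MDS and not on both moribund arrays. PRC2, PRC1 and NF-kappaB genes differed in sign between median, mean and test.

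Without Double_mutant the calls of immediate early (0.510), p53 (0.930), myeloid progenitor (0.586), neutrophil (0.0659), TLR (0.166), mitosis (0.586), DNA replication (0.363) and glycolysis genes (0.272) ended. Those of immediate early (0.350), p53 (0.447) and DNA replication genes (0.253) ended without Double_MDS, those of neutrophil (0.998), mast cell (0.965) and stromal genes (0.185) without Double_MDS_ML, and that of stromal genes without Ezh2_deleted or RUNX1_mutant (0.0723). With genes well above background on all 8 arrays the Hox (0.452), neutrophil (0.104), mast cell (0.133) and stromal calls (0.194) ended, leaving 9 of the 13. That of stromal genes also ended with normexp (0.0785), with the mean over probes (0.164) and with slide as a block.

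Read singly, Double_MDS minus Double_mutant lies within a slide and gave 1494 genes at least 2-fold higher and 2793 at least 2-fold lower. Insm1, a zinc-finger factor of endocrine cells, was higher by 10.01 or 1028-fold, the granzyme Gzmc by 6.58, Ackr1 by 5.93, Tnfrsf25 by 5.84, Bcar1 by 5.83 and Phlda1 by 5.79. Fbp1 (-8.5), B4galt6 (-7.42), Prom1 (-7.00), Mcpt4 (-6.83), As3mt (-6.58) and Gfi1 (-6.58) were lower. Median differences were 2.60 for immediate early genes (18 of 18 at least 2-fold higher, Egr2 4.83, Fosb 4.65), 2.55 for megakaryocyte genes (15 of 17, Gp6 4.96), 2.09 for NF-kappaB genes (14 of 22, Cxcl2 5.31) and 1.38 for CDK inhibitors (4 of 7, Cdkn1a 3.5, Cdkn2a 2.85). They were -2.98 for myeloid progenitor genes (15 of 18 at least 2-fold lower, Elane -5.49), -2.22 for dendritic cell genes (11 of 12), -1.81 for oncofetal genes (6 of 9), -1.40 for Hox genes (10 of 17, Hoxa7 -4.96), -1.22 for DNA replication genes (15 of 22) and -1.22 for mitosis genes (14 of 20). Neutrophil and mast cell genes gave -0.30 and -0.19. Tnni1 (at least 228-fold), Ttll11 (at least 58.6-fold) and Kcns3 (at least 46.9-fold) were on Double_MDS alone, and Nrp2 (at least 194-fold), Mansc1 (at least 138-fold) and Ambp (at least 77.5-fold) on Double_mutant alone.

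Double_MDS_ML minus Double_mutant, across slides, gave 1349 genes at least 2-fold higher and 2101 at least 2-fold lower. Lower there were S100a8 at -9.70, Chil3 at -8.97, Lrg1 at -8.86, Lcn2 at -8.79, Elane at -7.67 and Hdc at -7.87, beside Dmkn at -9.81 and Fbp1 at -9.11. Gdpd3 (9.24), Rbpms2 (7.12), Clec1b (6.49), Mmrn1, a platelet granule protein (6.08), Tdrp (5.76) and Slc4a11 (5.67) were higher. List medians were -6.12 for neutrophil (14 of 16 at least 2-fold lower), -4.85 for mast cell (12 of 15), -3.53 for myeloid progenitor (15 of 18) and -2.52 for monocyte genes (11 of 16). They were -1.80 for mitosis (19 of 20, Aurkb -2.61), -1.27 for Hox (10 of 17), 2.26 for megakaryocyte (14 of 18 at least 2-fold higher) and 0.79 for immediate early genes. On Double_MDS_ML alone were the imprinted Mest (at least 244-fold), Eif2s3y (at least 239-fold) and Syt13 (at least 148-fold), and on Double_mutant alone Wfdc21 (at least 1793-fold), Mogat2 (at least 403-fold) and Ltf (at least 383-fold). Between the moribund arrays, Double_MDS lay above Double_MDS_ML by medians of 6.01 for neutrophil, 4.14 for mast cell and 2.10 for NF-kappaB genes, against -0.11 for Hox and -0.04 for megakaryocyte genes.

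The wild-type CD45.1 arrays served as controls and asked whether normal cells differ with the mutant cells they share marrow with. B cell genes were higher in the double-mutant host than in the RUNX1_mutant host, Vpreb3 by 4.36, and so were stem and megakaryocyte genes, among them Vwf by 4.25 and the retinal dehydrogenase Aldh1a1 by 5.55. Neutrophil genes were lower, with Camp at -4.52, S100a8 at -4.49 and S100a9 at -4.07. Both arrays share a slide, and their pair gave 898 genes at least 2-fold higher and 1241 at least 2-fold lower (42.0% higher, or 60.1% with quantile normalization), an SD of log2 differences of 0.73. The medians were 2.65 for B cell (8 of 12 at least 2-fold higher), 2.00 for megakaryocyte (14 of 17), 1.79 for stem cell (21 of 28), 0.78 for immediate early, -2.53 for neutrophil (10 of 14 at least 2-fold lower), -1.31 for monocyte, -1.09 for myeloid progenitor and -1.07 for mast cell genes. Stromal genes gave 0.71, or -0.25 among genes well above background on both arrays. Cavin2 (4.66), Hspb1 (4.54) and Dlk1 (4.26) were also high in the double-mutant host, and the eosinophil ribonuclease genes Rnase2a (-4.27), Ear2 (-4.10) and Ear1 (-3.99) low. Mmrn1 (at least 35.3-fold), Gfra2 (at least 25.0-fold) and Evc2 (at least 24.8-fold) were there alone, and Ly6k (at least 133-fold), Fmr1nb (at least 84.6-fold) and Upk3bl (at least 63.7-fold) in the RUNX1_mutant host alone.

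Against WT, across slides, CD45.1_in_RUNX1_mutant gave 1568 genes at least 2-fold higher and 921 at least 2-fold lower (63.0% higher, or 46.9% with quantile normalization). Neutrophil genes had a median of 2.58 (Lcn2 4.10), myeloid progenitor genes 1.46 (Elane 4.48, Ms4a3 4.71) and mast cell genes 1.07 (the basophil protease Mcpt8 2.96). Megakaryocyte genes had -2.11 (Pf4 -2.97), stem cell genes -1.78 (19 of 27 at least 2-fold lower, Tie1 -3.45) and interferon-stimulated genes -1.12 (Ifi44 -3.15). Fmr1nb (6.42), Tctex1d1 (6.10), Dmkn (5.53), Hspa1a (4.82) and Igsf6 (4.75) were furthest up, and Aldh1a1 (-6.37), Bdh2 (-4.46), Arhgef25 (-3.77), Npdc1 (-3.60) and Gucy1a1 (-3.60) furthest down. Ly6k (at least 258-fold), Upk3bl (at least 104-fold) and Ldhc (at least 41.6-fold) were on this array alone, and Syt10 (at least 27.6-fold), Mmrn1 (at least 17.2-fold) and Trpc6 (at least 12.98-fold) on WT alone.

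CD45.1_in_double_mutant had the lowest count of the 6 arrays compared with WT, also across slides, with 639 genes at least 2-fold higher and 285 at least 2-fold lower (69.2% higher, or 54.5% with measured values in place of the bound). The heat shock genes Hspa1a (6.95) and Hspb1 (6.24) and the B lineage genes Jchain (5.62), Pou2af1 (4.59) and Ebf1 (3.55) were higher. The medians were 2.64 for B cell genes (10 of 12 at least 2-fold higher) and 1.51 for immediate early genes (13 of 17, Egr2 3.03). Gfra2 (4.35) and Lbhd2 (4.21) were further up, and Rps4l (-5.66), Plscr2 (-3.25), Ear2 (-3.21), Rnase2a (-3.05), Ear1 (-2.86) and Cdk5rap1 (-2.85) furthest down. Tdrd5 (at least 32.0-fold), Olfr1505 (at least 19.5-fold) and Bicdl1 (at least 17.5-fold) were on this array alone, and Syt10 (at least 49.0-fold), Rbm44 (at least 12.7-fold) and H2bc23 (at least 5.09-fold) on WT alone.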

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

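Of the tests in this part, those of B progenitor genes and of heat shock genes were chosen before their results were seen, and the slide, platelet, Hox dilution and RUNX1S291fs tests and the fit of interaction lists with slide as a block after.

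The first 9 results are lists for which the Ezh2 deletion effect differed between arrays with and without RUNX1S291fs, by camera on the interaction term over 29 lists. All 9 had adjusted p = 0.685 with an estimated correlation, and by fry 0 of 29 passed. The 4 arrays that define the term at month 4 split by slide, WT and Double_mutant on slide 1 and Ezh2_deleted and RUNX1_mutant on slide 2. With slide as a block, which leaves 1 residual degree of freedom, the 9 kept their sign, with adjusted p = 1.06e-10 (myeloid progenitor), 0.00251 (monocyte), 1.46e-07 (mitosis), 0.0138 (B cell), 0.0273 (T and NK cell), 1.12e-08 (NF-kappaB), 3.23e-08 (interferon-stimulated), 0.00692 (immediate early) and 0.00568 (p53 targets). Their medians with that block, in the same order, were 3.63, 3.82, 2.13, -2.25, -0.84, -2.32, -1.84, -1.04 and -1.01. The values that follow are those without it. Myeloid progenitor genes had adjusted p = 2.95e-07 and a median of 2.41, 17 of 18 positive. Monocyte genes had adjusted p = 0.00838 and a median of 1.74, 11 of 14 positive, with F13a1 at 6.47. Mitosis genes had adjusted p = 0.000106 and a median of 1.25, 19 of 20 positive, with Aurkb at 2.81 and Plk1 at 2.35. For B cell genes adjusted p = 4.04e-05, the median was -4.17 and 9 of 10 were negative. For T and NK cell genes adjusted p = 0.00626, the median was -1.46 and 9 of 12 were negative, with the receptor chain Cd3d at -3.27. For NF-kappaB genes adjusted p = 1.83e-09, the median was -2.35 and 19 of 22 were negative. Interferon-stimulated genes gave adjusted p = 0.00626 and a median of -0.81, with the chemokine Cxcl10 at -3.45. Immediate early genes gave adjusted p = 2.95e-07 and a median of -2.60, 15 of 17 negative. The p53 targets gave adjusted p = 0.00635 and a median of -1.09, with the cell cycle inhibitor Cdkn1a at -5.33 and the apoptosis gene Bbc3 at -4.67. Adjusted over the list alone, 1 gene each passed among myeloid progenitor, monocyte and NF-kappaB genes.

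A signal also lay in probes that carry no gene name, which were used in no comparison but the fits with every probe as a feature: 7906 of 28446 such probes (27.8%) were well above background on all 8 arrays, against 14695 of 27235 named probes (54.0%).

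B cell genes were high on the Ezh2_deleted array, with a mean level of 3.88 against -0.94 on WT and -2.03 on Double_mutant. They were next highest on CD45.1_in_double_mutant (1.57), wild-type cells on slide 2 like Ezh2_deleted, so a level above that of WT does not need Ezh2 deletion. The tables argue against slide as the whole cause, since the median difference from RUNX1_mutant on the same slide was 6.19. B-lineage cells in the sorted population may account for the pattern: of 13 B progenitor genes outside the list, 12 were measured, 7 were at least 2-fold higher than on WT and the median was 1.32, with Lef1 at 0.59 and Spib at 0.31 on Ezh2_deleted. The lineage gate should remove mature B cells where it holds that antibody, which is not given in the sources used here, and Cd24a (5.34) and Cplx2 (5.63), also among the 13, were bright on WT as well. An effect of Ezh2 loss in the progenitors themselves stays open and untested, as a single array has that genotype at month 4.

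On the moribund arrays megakaryocyte genes were high, with mean levels of 4.12 and 4.15 against 1.68 on Double_mutant, and Hox genes low. The tables argue against slide as the whole cause of the Hox part, since Double_MDS minus Double_mutant within slide 1 had a Hox median of -1.40. Platelets or megakaryocytes in the sorted population may account for the megakaryocyte part: of 14 platelet genes outside the list, 12 were tested, 11 were positive and 0 past the threshold, with a median of 1.62, the same without Mmrn1 and Trpc6, though such cells need to have passed a gate for c-Kit and Sca-1 (Gng11 2.39, P2rx1 2.06, Slc35d3 3.41). Dilution of Hox transcripts by cells of another type cannot be told apart from a fall within the cells, because the Hox median minus that of stem cell genes was -1.77 (from -2.02 and -0.25) while the 28 stem cell genes had a spread of 2.47. The difference from all genes was -1.89, but diluting cells share most genes with the sorted ones, so the reference was changed after that value was seen, and the disease stage itself stays open and untested.

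Immediate early genes were high on RUNX1_mutant (6.34), Double_MDS (6.36) and CD45.1_in_double_mutant (5.66), against 4.09 on WT. The tables argue against slide as the whole cause, as Double_MDS exceeded Double_mutant by a median of 2.60 within slide 1. A part due to slide stays open: the arrays of slide 2 had means of 4.75 to 6.34, each above WT (4.09) and Double_mutant (3.60) of slide 1. RUNX1S291fs in the sorted cells stays open as well. Double_mutant minus WT within slide 1 gave -0.49, but that is 1 array which also lacks Ezh2, and the interaction median was -2.60. The 0.78 between both wild-type CD45.1 arrays decides nothing alone. Stress during cell preparation also stays open. Over the 8 arrays the means of 17 immediate early and 9 of 10 heat shock genes chosen had Pearson's r = 0.293. Its 95% interval was -0.52 to 0.83 and its exact two-sided permutation p = 0.463 (adjusted p = 0.463 over 2 relations, rho = 0.214, p = 0.619). That r was under the bound of 0.3 set for excluding stress by less than its spread. It was 0.669 without Double_MDS and RUNX1_mutant, and slides hold too few arrays for their own value. Of the 9, Dnajb1 was highest on the named arrays (7.33 to 7.79, others 5.49 to 6.62), Bag3 lowest on Double_MDS (-1.96).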

How the results depend on the processing

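The Y-linked term, the kind of recipient as a block, the fit without the CD45.1_in_RUNX1_mutant and Ezh2_deleted arrays, and every probe as a feature were chosen after the data were seen, as was slide as a block for interaction lists, the other alternatives before. Replicate numbers pair nothing here, as each group has replicate 1 alone. Competitor and mutant cells come from recipients of the same kind in 2 cases, but the labels do not say that they come from the same mice. A fit with that kind of recipient as a block left 2 residual degrees of freedom (1 with the interaction). It gave 0 genes for each of the 4 effects, against 2 for RUNX1S291fs and 250 for stage in the main fit. The block marked RUNX1_mutant and Double_mutant recipients at month 4 but not the moribund mice, so for stage it is no adjustment for recipient. Counts of genes and lists stayed within 1.5 times in 162 of their repeats and moved further in 45. Other values gave the same result in 5111 repeats, moved in 218, lost a call in 251, gained a call in 102 and reversed in 1: the stromal median of CD45.1_in_double_mutant minus CD45.1_in_RUNX1_mutant, -0.25 with both arrays well above background. Signal over background limits dim genes, whose differences are bounds. Normexp moved the median of all genes by -0.08 (WT) to -0.24 (CD45.1_in_RUNX1_mutant) and quantile normalization by -0.12 to 0.07.

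For Ezh2 deletion and the interaction, 0 genes passed under every alternative that ran. The interaction could not be fitted without Ezh2_deleted, RUNX1_mutant or Double_mutant, or without CD45.1_in_RUNX1_mutant and Ezh2_deleted together. The 2 genes of RUNX1S291fs became 1 with normexp (higher, neither of the 2), 5 with quantile normalization, 0 with no filter on dim probes, 0 with genes well above background on all 8 arrays, which leaves both untested, 1 with the mean over probes, 0 with an intensity trend, 0 with slide as a fixed block, 0 as a random block, 4 on month 4 arrays, 9 without the stage term, 0 with the Y-linked term, 0 with the kind of recipient as a block, 0 without CD45.1_in_RUNX1_mutant and Ezh2_deleted, and 4 with every probe. Leaving out 1 array gave 0 to 10, where a lone array is assumed to vary like the others. Apart from that filter, the cause was not tested. Tmprss4 ranged from -5.72 to -1.41 and Il18r1 from -4.94 to -2.78.

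The 250 stage genes became 150 with no filter on dim probes (140 shared), 152 with genes well above background on all 8 arrays (131 shared; fewer genes tested) and 75 with slide as a fixed block (35 shared), where Double_MDS_ML, alone on slide 3, no longer counts. With the kind of recipient as a block, which leaves the moribund mice unmarked, there were 0. As a random block slide gave 218, all of them among the 250, and quantile normalization 242 (221 shared). Leaving out 1 array gave 0 (Double_mutant) to 381 (Double_MDS_ML). For Ezh2 deletion, RUNX1S291fs and stage, camera's 8, 13 and 13 lists became 0, 0 and 0 with an estimated correlation and 0, 0 and 2 with fry, which asks another question. Of these lists 5 of 8 and 9 of 13 kept the call without the stage term, which has no stage effect to test, and 6 of 8, 12 of 13 and 9 of 13 with genes well above background on all 8 arrays. Calls were gained as well: there were 12, 16 and 15 lists with no filter on dim probes and 10, 17 and 14 with normexp. Normexp lowered the genes at least 2-fold apart to 868 for Ezh2_deleted minus WT, 1167 for RUNX1_mutant minus WT, 1550 for Double_mutant minus WT, 1380 for Double_mutant minus RUNX1_mutant, 1890 for Double_mutant minus Ezh2_deleted, 1567 for CD45.1_in_RUNX1_mutant minus WT, 386 for CD45.1_in_double_mutant minus WT and 1213 between the CD45.1 arrays. The other normexp pairs, 2994 for Double_MDS and 2412 for Double_MDS_ML minus Double_mutant, stayed within 1.5 times. For these counts the cause was not tested.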

Other observations

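The test in this part, splits of the arrays, was chosen after the results were seen. Cdkn2a was well above background on the 4 Ezh2-deleted arrays, at 0.77 on Ezh2_deleted, -0.92 on Double_mutant, 1.92 on Double_MDS and 2.41 on Double_MDS_ML, and of the others on CD45.1_in_double_mutant alone, at -3.00. Hmga2 was 2.16 on Ezh2_deleted, 1.84 on RUNX1_mutant, 1.13 on Double_mutant and 1.99 on Double_MDS, against 0.03 on Double_MDS_ML, -0.16 on WT, -0.36 on CD45.1_in_double_mutant and -1.57 on CD45.1_in_RUNX1_mutant. Igf2bp3 was well above background on Double_mutant (-0.08) and Ezh2_deleted (-2.50) alone. Cpa3 lay at 6.76, 6.39, 8.47 and 6.85 on RUNX1_mutant, Double_mutant, Double_MDS and Double_MDS_ML, against 1.45 on WT and 2.24 on both CD45.1 arrays. These genes were singled out after their values were seen.

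Double_MDS minus WT, within slide 1 and not among the pairs chosen at the start, had 1933 genes at least 2-fold higher and 2462 at least 2-fold lower. List medians were 4.50 for neutrophil, 2.73 for megakaryocyte, 2.26 for mast cell, 1.95 for immediate early and 1.80 for CDK inhibitor genes. Lowest were -2.81 for dendritic cell, -2.42 for lymphoid-primed and -1.99 for Hox genes. Double_mutant minus CD45.1_in_double_mutant, added after the results were seen, crosses slides and sets mutant against competitor cells of double-mutant recipients. It gave 1286 genes at least 2-fold higher and 1305 at least 2-fold lower, with list medians of 4.74 for neutrophil, 3.23 for mast cell and 1.40 for myeloid progenitor genes, against -3.93 for B cell, -2.10 for immediate early and -1.94 for dendritic cell genes. Of the sex-linked controls, the Y-linked Ddx3y and Eif2s3y were well above background on Ezh2_deleted (1.74 and 2.71) and Double_MDS_ML (1.57 and 3.22) alone, and Xist on the 6 other arrays (1.1 to 2.76). Sex is not given in the sources used here. Syt10 was well above background on WT alone (1.30). The mean of erythroid genes followed that of neutrophil genes over the 8 arrays, Pearson's r = 0.934 (exact permutation p = 0.00122, two-sided; rho = 0.810, p = 0.0218; adjusted p = 0.00243 over 2 relations), and r = 0.877 without Double_MDS_ML and Double_mutant. Examples are mean levels of 1.98 on Ezh2_deleted, 1.97 on Double_mutant and 1.73 on Double_MDS, where neutrophil genes lay at 2.00, 3.44 and 2.85, against 0.97 on WT, 0.96 on CD45.1_in_double_mutant and 0.47 on Double_MDS_ML, where they lay at -1.06, -1.06 and -2.73. The relation was picked after these means were seen, so its p is no test.

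Other splits of the 8 arrays into 4 against 4, 34 of 35 of which could be fitted, gave a measure of chance. The 2 genes of RUNX1S291fs were reached by 1 of 34 splits, the real one (highest other 0), the smallest share these splits can give. The count was 0 with slide or the kind of recipient as a block or without any 1 of 5 arrays, so the 2 calls depend on the model. The 0 genes of Ezh2 deletion (321 at an unadjusted p under 0.05 in limma) are reached by any split, 34 of 34 (highest other 3), so for them the splits test nothing. The 8 lists of Ezh2 deletion were reached by 25 of 34 (highest other 13) and the 13 lists of RUNX1S291fs by 10 of 34 (highest other 20), so chance cannot be excluded for these lists. The split of slide 2 against the other slides gave 0 genes and 3 lists in the Ezh2 fit and 0 genes and 7 lists in the RUNX1S291fs fit, fewer lists than the real ones.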
